A study of Homo sapiens with 18 samples.

How the data were processed

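RNA was sequenced from sorted HBL1 lymphoma cells after 4 days in organoids, in 18 libraries that fell into 6 groups of 3. The groups were the 3 matrices REDV, GFO and RGD, each with and without stromal cells presenting CD40 ligand. The sample labels give each library's matrix, co-culture state and replicate number, and the series' design text calls the replicates biological. RNA was taken from the sorted cells with TRIzol, per the labels' protocols.

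The deposited values were whole-number read counts, and per the submitters' processing notes they came from bcl2fastq, TopHat2 2.1.1 and HTSeq 2.0.1 on the human build hg38. The counted unit was the exon, so the deposited table held 2206933 exon records, 1 for each exon of each transcript, of which 37620 held reads, plus 5 summary records of HTSeq. The strand setting of the counting, the annotation release and the library kit are not given in the sources used here. Reads that overlapped more than 1 record were counted as ambiguous and not assigned. Each transcript has its own records, so reads on an exon shared by transcripts of a gene were not assigned. A gene's counts therefore come from stretches covered by 1 record, and a change in them need not be a change of the whole gene.

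Of the uniquely aligned reads of a library, 1.67% to 2.07% were assigned to exon records, 1.45% to 1.68% were ambiguous and 96.2% to 96.9% overlapped no record. Between 47.8% and 48.8% of a library's reads were not aligned, and 12.2% to 15.6% of aligned reads had more than 1 place. These summary records were left out of library sizes and tests. Uniquely aligned reads numbered 14230555 to 48573973 per library and exon counts 237981 to 1007040, so 1 count was a large step for most genes.

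Exon records were summed to genes with the names of the RefSeq gene table of the same assembly. By reads, 69.8% were matched by transcript accession, 0.441% by another version of an accession and 26.3% by a symbol inside the identifier, while 3.43% had an accession and 0.110% an identifier without a match and kept their identifiers. This gave 20330 genes or unmatched identifiers with reads. GENCODE release 29 on GRCh38, the same build as hg38, served to find which gene lies on the other strand of a counted exon or gene, and gene coordinates are 1-based positions on hg38. A partner is called opposite only where both strands are annotated, and overlapping where the strand of the counted gene was not given. No per-sample column was left unused (0 columns).

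The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with TMM scaling, low counts filtered by group with a minimum count of 10, and 1 fit of 6 group means over all 18 libraries with 12 residual degrees of freedom. The filter kept 3122 genes, which held 97.0% of the exon counts, and required about 22.6 CPM (counts scaled to library size). The common biological coefficient of variation was 0.161. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg), and every adjusted p of a gene or a count of called genes comes from this test unless another is named. The 10 contrasts were co-culture within each matrix, GFO and RGD against REDV with and without co-culture, co-culture averaged over the 3 matrices, and the difference of the co-culture change between GFO or RGD and REDV. Log2 fold changes are given with their standard errors, and CPM as mean ± SD over the 3 libraries of a group. Floors of 3 counts over a group stand for groups at 0, and ratios with 1 to 3 counts carry exact 95% intervals; floors and intervals cover counting error only.

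Named genes followed a rule set before the data were examined, by size of change or by p among called genes whose library ranges did not overlap, plus members of gene lists with the smallest p and 31 genes of B-cell signalling and adhesion. Of those 31, 4 passed the filter (CD40LG, NFKBIA, BIRC3 and TNFAIP3). Genes named because they lie opposite a list member, and those in the closing section said to be so, were chosen after the data were seen. Of the gene lists fixed beforehand, 34 in all, 7 had at least 5 tested members under their own names. These were NF-kB target genes, immediate early and heat shock genes, ER stress, mitosis, MYC and ribosome biogenesis, cytosolic ribosomal proteins and mitochondrially encoded mRNAs. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists within a contrast.

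Other fits set before the data were examined were DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, the replicate number as a block, only the compared groups in the fit, each library left out in turn, and camera with an estimated correlation, fry or the block. After the data were seen, scaling by all uniquely aligned reads, leaving out mitochondrial genes, leaving out the 3 libraries with over 14% multi-mapped reads, thinning each library to 237981 exon counts, and lists built from the gene on the opposite strand were added. The test was checked on simulated counts for 3122 genes drawn with the real means, in which 50 genes changed at each fold. For co-cultured REDV against REDV it called 14% of genes changed 1.5-fold, 64% at 2-fold, 90% at 4-fold and 92% at 8-fold, and 0.205% of unchanged genes. For GFO against REDV these shares were 16%, 44%, 96%, 98% and 0.376%. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.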

Results

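HBL1, an established human line of activated B-cell-like diffuse large B-cell lymphoma, was grown for 4 days in organoids that each held 40000 lymphoma cells. The organoids were built in 3 matrices labelled REDV, GFO and RGD, of which REDV was the control, and the design text spells GFO out as GFOGER. These are names of short peptide motifs of fibronectin or collagen that bind integrins, the receptors by which cells hold on to matrix. In each matrix the lymphoma cells were cultured alone or with 40000 stromal cells presenting CD40 ligand, the T-cell signal that activates B cells through CD40. The series asks how the surroundings of B-cell lymphoma cells weaken inhibitors of MALT1, a protease of NF-kB signalling, and no library carried a drug label. Sorted lymphoma cells gave 18 RNA libraries, 3 biological replicates in each of 6 groups.

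Exon counts per library ranged from 633568 to 800802 in REDV, 539158 to 709471 in GFO and 625873 to 1007040 in RGD. With co-culture they ranged from 297960 to 326430 in REDV, 263231 to 345970 in GFO and 237981 to 321182 in RGD. The 9 co-culture libraries held fewer exon counts than the 9 others (mean 306021 against 726450; two-sided exact permutation p = 4.11e-05, the smallest this design can give). Mitochondrial records took 16.3% ± 1.43 of exon counts with co-culture and 27.3% ± 2.93 without it (SD, n = 9 each; exact permutation p = 4.11e-05). Protein-coding genes with no annotated gene on the opposite strand, such as NFKBIA, JUN and TNFRSF13B, took 2.41% ± 0.262 of tested counts with co-culture (lowest library 2.14%) and 1.95% ± 0.0695 without it (highest library 2.06%; exact permutation p = 4.11e-05). Tested counts include mitochondrial counts, so the lower mitochondrial share with co-culture raises this share by itself. The share without mitochondrial counts was not tested. The sheet numbers in the library labels ran from 1 to 6 and 16 to 18 with co-culture and from 22 to 32 without it, so run order or lane and co-culture cannot be told apart. The first principal component held 44.5% of the variance and separated the co-culture libraries from the rest.

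Where the counted reads lay bears on every gene named here. Of the 9292241 exon reads, 40.6% were in long noncoding RNA genes, 23.5% in protein-coding genes, 24.2% in mitochondrial genes and 4.59% in genes classed as antisense. MT-ND6, the mRNA encoded on the opposite strand to the other mitochondrial mRNAs, had 1490 reads per base, against 28.9 to 269 (median 96.5) for the 11 others. Among exon records that could be placed on the annotation, which held 2506460 of the exon reads, 80.3% of reads were in records with an annotated exon on the opposite strand, and such records made up 10.4% of the placed exon length. Genes with such a partner are therefore uncertain, and the partner is named where the gene is first discussed. Counting on the wrong strand, weighed in the closing section, would leave out most mRNA reads of every gene. The counts of genes without a partner, such as NFKBIA, JUN and TNFRSF13B, are therefore uncertain as well. Some partners were matched by locus only: for ILDR1, ZNF518A, XPA, UQCC6, HOOK2, FSIP1, DNAI7 and TNFAIP3 no counted exon could be placed. For TIMMDC1, NFE2L3, BOP1, KIF11 and POLQ the counted exons were placed and had no exon opposite them, so the partner's locus overlaps the gene but not the counts. The overlaps come from GENCODE, and in the RefSeq table, which gave the printed coordinates, UQCC6, NFE2L3, MTERF2, NPPA, RPS23 and SRRM2 do not overlap their partners.

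**Figure D1:**
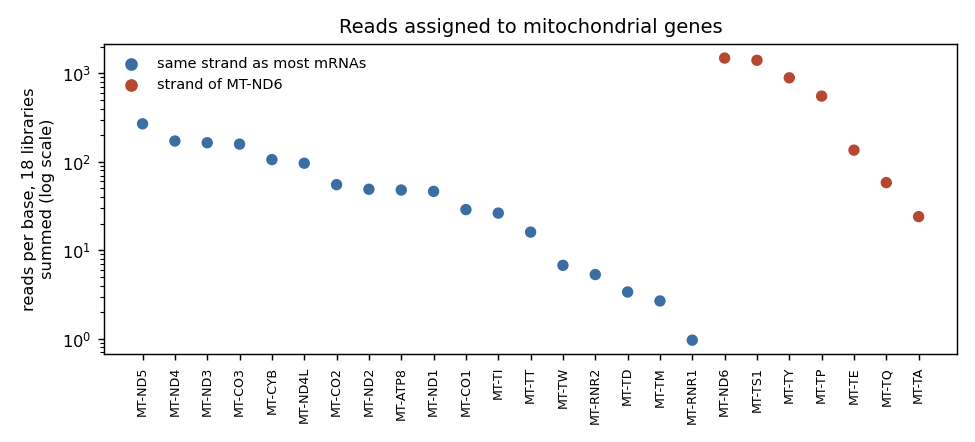
Reads per base of each mitochondrial gene, summed over the 18 libraries, on a log axis and coloured by the strand that encodes it. MT-ND6 stands at 1490 and the other 11 mRNAs between 28.9 and 269.

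Co-culture in the control matrix addressed what stromal cells presenting CD40 ligand do to the lymphoma cells. CD40LG, the gene of CD40 ligand itself (hg38 chromosome X, 136648158 to 136660390, plus strand), had 0 counts in the REDV libraries and 28.5 ± 13.6 CPM with co-culture (26 counts, n = 3 each), at least 18.9-fold higher. The added stromal cells present this ligand, so its reads may come from stromal RNA and need not be a change in the lymphoma cells. NFKBIA, the NF-kB inhibitor that NF-kB itself induces (chromosome 14, 35401513 to 35404749, minus strand), rose from 241 ± 23.4 to 503 ± 76.0 CPM, a log2 change of 1.06 ± 0.17 (SE, edgeR adjusted p = 8.61e-06). The circadian repressor NR1D1 (chromosome 17, 40092793 to 40100589, minus strand), whose last exon lies opposite the thyroid hormone receptor gene THRA, rose 14.4-fold, to 351 ± 94.4 CPM (log2 3.85 ± 0.27). ILDR1 (chromosome 3, 121987323 to 122061655, minus strand), a tricellular junction gene that lies opposite the co-stimulation gene CD86, rose from 2.94 ± 2.52 to 58.3 ± 19.2 CPM. Among genes that fell, TNFRSF13B (chromosome 17, 16939081 to 16972118, minus strand), which encodes the BAFF and APRIL receptor TACI, went from 1270 ± 263 to 500 ± 67.0 CPM.

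In REDV, edgeR called 479 genes higher and 420 lower with co-culture out of 3122 (53.3% higher), and 284 higher and 490 lower (36.7%) without the filter on low counts, so the balance rests on the filter. Further genes at 0 counts without co-culture were LINC01342 (at least 36.4-fold higher), KRT7-AS opposite the keratin gene KRT7 (20.4), NR2F1 opposite its antisense RNA (19.7), the potassium channel gene KCNG4 (18.2) and LIF-AS1 opposite the cytokine gene LIF (18.2). TAMALIN-AS1 (chromosome 12, 52006250 to 52007655), which overlaps the scaffold gene TAMALIN, rose by 4.50 ± 0.25 log2 units (adjusted p = 2.51e-17), and ZNF333, opposite the adhesion receptor gene ADGRE2, rose by 2.98 ± 0.22 (adjusted p = 5.48e-14). The immediate early genes IER5 and JUN rose 5.11-fold and 5.84-fold, and the stress transcription factor gene ATF5, partly opposite NUP62, rose 2.88-fold. ZNF740 (chromosome 12, 53180722 to 53195142, plus strand), counted in an exon opposite the integrin subunit gene ITGB7, fell by 1.54 log2 units, from 10440 ± 2400 to 3592 ± 735 CPM. ZNF518A, opposite the B-cell receptor adaptor gene BLNK, fell by 1.83, and XPA, a DNA repair gene opposite NCBP1, fell by 2.04. HNRNPA1P59 and DLSTP1, pseudogenes that may share reads with their parent genes, fell by 2.94 and 1.74. BIRC3, an NF-kB target that limits cell death, had 30.9 ± 13.6 against 13.8 ± 4.36 CPM and was not called (log2 1.13 ± 0.50, adjusted p = 0.0843). Without the 3 libraries with over 14% multi-mapped reads (co-cultured REDV replicates 1 and 3, co-cultured GFO replicate 2), 1 library of the co-cultured REDV group was left, 373 genes were called, and JUN was no longer called (log2 1.90, adjusted p = 0.102).

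**Figure D2:**
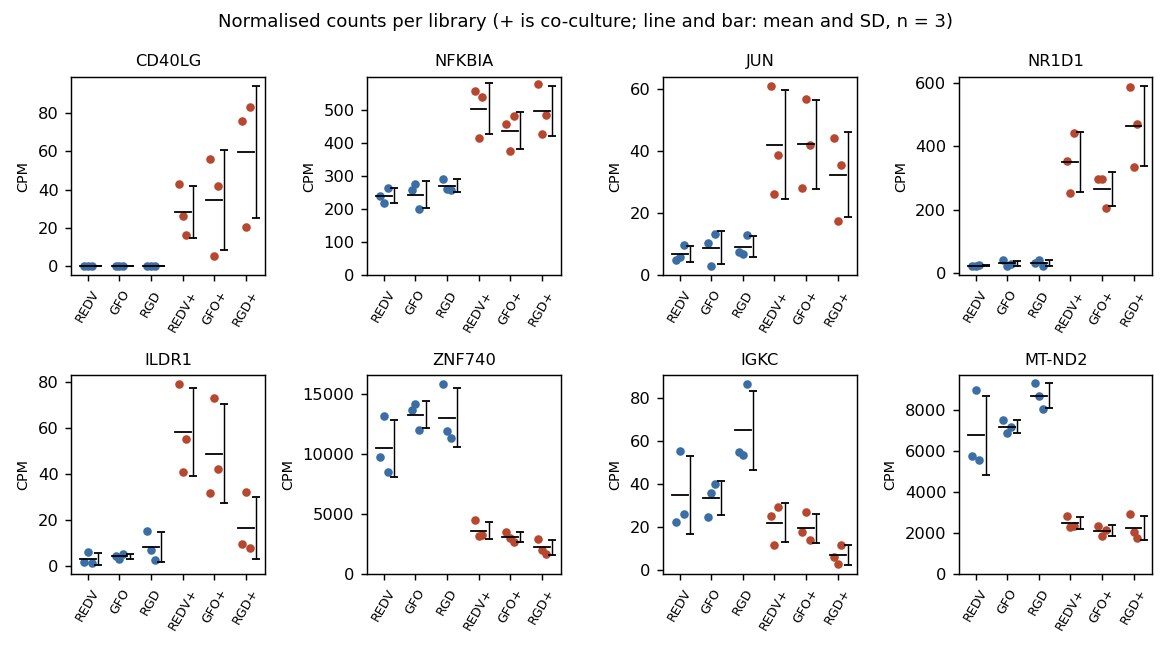
CPM of CD40LG, NFKBIA, JUN, NR1D1, ILDR1, ZNF740, IGKC and MT-ND2 in each of the 18 libraries by group, with the group mean and SD. CD40LG is at 0 in all 9 libraries without co-culture, and ZNF740 and MT-ND2 are lower with co-culture in each matrix.

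Co-culture in GFO asked the same of cells in the collagen-like matrix. CD40LG again had 0 counts without co-culture and 34.5 ± 26.2 CPM with it (33 counts, n = 3 each), at least 18.8-fold higher. Here too its reads may come from stromal RNA. NFKBIA rose from 244 ± 39.5 to 437 ± 55.1 CPM (log2 0.84 ± 0.18, adjusted p = 0.000296) and BIRC3 (chromosome 11, 102317484 to 102339403, plus strand) from 10.5 ± 5.52 to 36.6 ± 10.5 CPM (log2 1.73 ± 0.50, adjusted p = 0.00792). TIMMDC1 (chromosome 3, 119498547 to 119525090, plus strand), a complex I assembly gene whose locus, but not its counted exons, overlaps the co-stimulation gene CD80, rose 6.35-fold, and ILDR1, opposite CD86, rose 11.6-fold. CDC20, which activates the anaphase-promoting complex, rose 3.70-fold, and PPP1R15A, which restores translation after stress, 2.96-fold. HLA-DQB1-AS1 (chromosome 6, 32659880 to 32660729, plus strand), opposite the class II gene HLA-DQB1, fell from 820 ± 45.8 to 235 ± 35.8 CPM.

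In GFO, edgeR called 485 genes higher and 428 lower with co-culture, and 326 and 482 (40.3% higher) without the filter on low counts. JUN rose 4.80-fold and IER5 4.57-fold, whereas EGR1 (chromosome 5, 138465479 to 138469303, plus strand), another immediate early gene, fell by 1.91 log2 units (adjusted p = 0.000665). TNFRSF13B fell by 2.04, ZNF740 by 2.12 and EXOSC9, opposite the cyclin gene CCNA2, by 1.40 log2 units. The chromatin gene HMGN2 fell by 3.11, and FLG2, of the filaggrin family, had 3 counts with co-culture and 53 without it, a ratio of 10.4 (95% counting interval 3.35 to 51.8). HMGN2 has many pseudogene copies and is uncertain for that reason. Without co-cultured GFO replicate 3, BIRC3 was no longer called (log2 1.47, adjusted p = 0.0596). Scaling by all uniquely aligned reads raised the median change of all genes by 0.126 log2 units and the share of higher calls from 53.1% to 65.2% (614 higher, 327 lower).

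In RGD, the integrin ligand of fibronectin, CD40LG went from 0 counts to 59.8 ± 34.3 CPM with co-culture (52 counts, n = 3 each), at least 40.4-fold higher. As in the other matrices, these reads may come from stromal RNA. NFKBIA rose from 270 ± 19.1 to 496 ± 76.3 CPM (log2 0.87 ± 0.17, adjusted p = 0.000156), while BIRC3 was not called (log2 0.21 ± 0.50, adjusted p = 0.785). IGKC (chromosome 2, 88857361 to 88857683, minus strand), the constant region of the kappa light chain, fell from 64.9 ± 18.5 to 7.04 ± 4.53 CPM (log2 -3.25 ± 0.52, adjusted p = 5.10e-06). The co-cultured RGD libraries held only a few IGKC reads each (2.92 to 11.9 CPM). In REDV its libraries overlapped, at 22.5 to 55.5 CPM without co-culture and 11.7 to 29.1 CPM with it. PLCG2 (chromosome 16, 81739041 to 81962685, plus strand), the phospholipase of the B-cell receptor, fell from 84.9 ± 40.6 to 16.7 ± 11.3 CPM. The endoplasmic reticulum chaperone genes HSPA5 (chromosome 9, 125234853 to 125241343, minus strand) and HSP90B1 fell by 2.21 and 1.28 log2 units.

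With co-culture in RGD, 456 genes were called higher and 439 lower by edgeR (50.9% higher), and 260 and 445 (36.9%) without the filter on low counts. ZBTB20-AS1, opposite the repressor gene ZBTB20, rose from 0 counts to 116 ± 21.3 CPM, at least 80.9-fold, and LIF-AS1 at least 29.5-fold. TIMMDC1 had 37 counts with co-culture and 1 without it, a ratio of 86.3 (14.6 to 3500). WAKMAR2 (chromosome 6, 137823669 to 137868233, minus strand), opposite the NF-kB inhibitor gene TNFAIP3, rose 2.61-fold, and CFLAR-AS1 (chromosome 2, 201140289 to 201157792, minus strand), opposite the caspase inhibitor gene CFLAR, 2.04-fold. DEXI, opposite the class II regulator gene CIITA, rose 2.16-fold. ILDR1, opposite CD86, ranged from 2.61 to 15.3 CPM without co-culture and from 7.92 to 32.1 CPM with it, so its libraries overlapped in RGD. NOP58, a core protein of small nucleolar RNA particles, had 1 count with co-culture and 57 without it, a ratio of 24.4 (4.21 to 982), and the nucleolar gene NCL fell by 1.64 log2 units. EHD3, of endosome recycling, fell by 3.34, TNFRSF13B by 1.58 and ZNF740 by 2.57 log2 units. A fit on the RGD libraries alone called 592 genes, and 594 were called without co-cultured RGD replicate 2.

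Averaged over the 3 matrices, 813 genes were called higher and 781 lower with co-culture (51.0% higher), and 764 and 1213 (38.6%) without the filter on low counts. NFKBIA rose by 0.92 ± 0.10 log2 units (edgeR adjusted p = 3.92e-10), BIRC3 by 1.02 ± 0.29 (adjusted p = 0.00329), JUN by 2.19 ± 0.29 and IER5 by 1.94 ± 0.27. NR1D1 rose 12.2-fold, ZNF333 6.94-fold, and TAMALIN-AS1 16.7-fold. EGR1 fell by 1.69, TNFRSF13B by 1.66, ZNF740 by 2.08 and ZNF518A by 1.62 log2 units. NPPA, a natriuretic peptide gene opposite CLCN6, fell by 1.94, XPA by 2.02, and DNAI7, opposite the IRAG2 gene of lymphoid cells, by 1.61. Of 101 named results called in this contrast, 76 stayed called in every refit. The share of counts in protein-coding genes with no opposite gene, the class of NFKBIA, BIRC3 and JUN, was also higher in every co-culture library (mean 2.41% against 1.95%), and how much of their rise goes with that share was not tested. That share is of counts that include mitochondrial ones, so it rises in part because mitochondrial records took 16.3% of exon counts against 27.3%.

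Of 42 fibroblast and stromal markers 2 were tested under their own names, too few for a list test. The collagen gene COL5A1, opposite COL5A1-AS1, rose by 0.87 ± 0.20 log2 units on average (edgeR adjusted p = 0.000383), and IGFBP7, a secreted growth factor binding protein gene counted opposite POLR2B, was not called (0.01 ± 0.10, adjusted p = 0.951). A further 4 tested genes lie opposite or over a marker, of which 3 were higher and 1 lower. ACTA2-AS1, opposite the smooth muscle actin gene ACTA2, rose by 1.41 ± 0.34, and LOC124904423, which overlaps the calcium-binding protein gene S100A6, by 1.69 ± 0.13. FSIP1, opposite the matrix gene THBS1, was at least 18.2-fold higher in REDV and at least 6.26-fold in GFO, each over 0 counts, and had 20 against 2 counts in RGD, a ratio of 23.3 (5.67 to 206). LOXL2-AS1, counted mostly opposite the collagen crosslinking gene LOXL2, fell by 1.02 and was not called after thinning (adjusted p = 0.0823).

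The counts of all 12 tested mitochondrial mRNAs, which encode subunits of the respiratory chain and ATP synthase, fell in the average over the matrices (12 lower adjusted over the list alone), with a median change of -1.11 log2 units. MT-ND2 (chromosome MT, 4470 to 5511, plus strand) fell by 1.72 and MT-CYB by 1.45 log2 units. By matrix, 11 fell in REDV, with 1 not called (12 adjusted over the list alone), 12 in GFO (12) and 12 in RGD (12). With camera the adjusted p was 4.48e-06 in REDV, 4.08e-08 in GFO, 5.09e-11 in RGD and 1.25e-08 on average. With an estimated correlation the adjusted p was 0.796, 0.545, 0.161 and 0.487, so none of these calls held. The same libraries differed in depth and in sequencing number, and nuclear copies of mitochondrial genes could take part of the reads. MT-ND6, the mRNA of the other strand, had 1490 reads per base against at most 269 for the rest. The counts of all 12, MT-ND6 included, are therefore as uncertain in origin as those of genes with an opposite partner.

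Of 6 tested NF-kB target genes, 3 were higher (NFKBIA, BIRC3 and TNFAIP3), 2 lower and 1 not called on average, with the same counts adjusted over the list alone. The camera adjusted p was 0.824, and 0.846 with an estimated correlation. The called lower members were SOD2, a mitochondrial dismutase gene counted mostly opposite WTAP (log2 -0.51 ± 0.09), and NFKBIE, another inhibitor (log2 -0.46 ± 0.15). TNFAIP3, which lies opposite WAKMAR2, was called at 0.41 ± 0.15 (adjusted p = 0.0242). That call ended without REDV replicate 2 (adjusted p = 0.0594), without co-cultured REDV replicate 2 (0.0880) and without the filter on low counts (0.527). NFKBIE was not called after thinning (adjusted p = 0.116).

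Of 6 immediate early and heat shock genes, JUN and IER5 rose, EGR1 fell and 3 were not called in the average, with the same counts adjusted over the list alone (camera adjusted p = 0.700; 0.846 with an estimated correlation). Of 5 mitosis genes, 1 was higher and 2 lower on average, also adjusted over the list alone (camera 0.824; adjusted p = 0.846 with an estimated correlation). The higher member was CDC20 (log2 1.01 ± 0.23), and the lower ones were the cyclin gene CCNA2, opposite EXOSC9 (-0.47 ± 0.12), and the spindle motor gene KIF11, opposite the pseudogene RPL11P4 (-0.65 ± 0.23). After thinning, neither CDC20 (adjusted p = 0.0557) nor KIF11 (0.261) was called, and KIF11 was not called without the 3 libraries with over 14% multi-mapped reads (0.181).

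Of 5 MYC and ribosome biogenesis genes, NOP58 and BOP1, the latter opposite the transcription factor gene SCX, fell on average and 3 were not called (3 lower adjusted over the list alone; camera adjusted p = 0.448; adjusted p = 0.692 with an estimated correlation). By matrix, 3 of 5 were lower in RGD (4 adjusted over the list alone), with a median of -1.05 log2 units. The camera adjusted p was 0.0555 there, and 0.161 with an estimated correlation. In REDV 1 of 5 was lower (1 adjusted over the list alone), with a median of -0.45 (camera 0.521, and 0.796 with an estimated correlation). In GFO edgeR called 0 of 5, and 0 adjusted over the list alone, with a median of 0.41 (camera 0.865, and 0.871 with an estimated correlation). The direct tests of a different co-culture change than in REDV called 0 of 5 for RGD and 0 of 5 for GFO. Their camera adjusted p was 0.206 for RGD and 0.189 for GFO, and 0.320 and 0.554 with an estimated correlation. A difference between the matrices was therefore not called for this list. Of 5 cytosolic ribosomal protein genes, RPL28 and RPS23 fell and 3 were not called, with 2 lower adjusted over the list alone (camera 0.448; adjusted p = 0.692 with an estimated correlation). RPL28 fell by 1.24 log2 units, and its locus overlaps the ubiquitin enzyme gene UBE2S on the other strand, but the counted exons that could be placed do not. RPS23, counted mostly opposite ATG10, was not called after thinning (adjusted p = 0.105).

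Of 6 ER stress genes, 4 fell with co-culture in RGD and 2 were not called (4 lower adjusted over the list alone), and the camera adjusted p was 0.0356 (adjusted p = 0.161 with an estimated correlation). The members that fell were the chaperone genes HSPA5, HSP90B1 and CALR and the mannosidase-like gene EDEM1. CALR, counted mostly opposite an uncharacterised gene, lost its call without RGD replicate 3 (adjusted p = 0.216), without co-cultured RGD replicate 3 (0.171), after thinning (0.204), in a fit on the RGD libraries alone (0.0794) and with DESeq2 (0.0505). EDEM1, also opposite an uncharacterised gene, lost it without RGD replicate 2 (0.0564), co-cultured RGD replicate 2 (0.0655) and co-cultured RGD replicate 3 (0.0730). In GFO 2 members were higher, 0 lower and 4 not called, also adjusted over the list alone, with a median of 0.22 log2 units (camera 0.772; adjusted p = 0.871 with an estimated correlation). In REDV edgeR called 0 of 6, and 0 adjusted over the list alone (camera 0.687; adjusted p = 0.796 with an estimated correlation). On average over the matrices 1 member was higher and 3 were lower, also adjusted over the list alone (camera 0.448; adjusted p = 0.692 with an estimated correlation).

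The co-culture changes of the 3 matrices were compared across the 3122 genes, which are not independent replicates. These contrasts share no libraries. In each of them, however, the co-culture libraries also differed from the others in exon counts and sheet numbers. Agreement can therefore come from run, lane or depth as well as from co-culture. Pearson's r was 0.797 between REDV and GFO, 0.719 between REDV and RGD and 0.747 between GFO and RGD. Over all 20330 genes without the filter these were 0.220, 0.208 and 0.208. NFKBIA, TNFRSF13B, ZNF740 and MT-ND2 were called in the same direction in all 3 matrices. REDV and GFO shared 289 genes called higher, against 74.4 for independent lists, and 268 called lower, against 57.6, with 0 called in opposite directions. REDV and RGD shared 261 higher (70.0) and 212 lower (59.1), with 7 in opposite directions, and GFO and RGD shared 281 (70.8) and 248 (60.2), with 7.

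**Figure D3:**
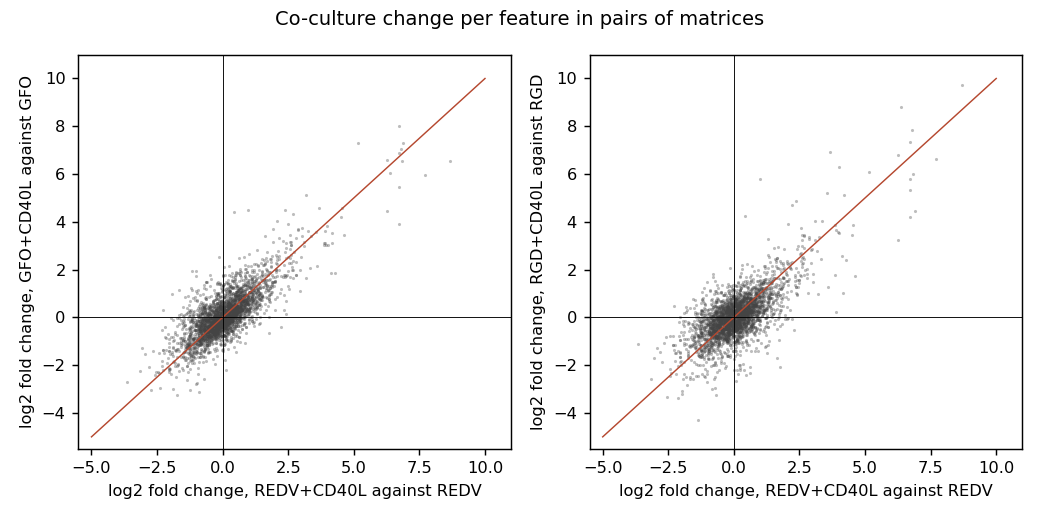
Log2 fold change with co-culture in REDV (horizontal) against GFO and against RGD (vertical), 1 point per gene for 3122 genes. Pearson's r is 0.797 with GFO and 0.719 with RGD.

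GFO against REDV without co-culture asked what the collagen-like ligand alone does. UQCC6 (chromosome 12, 103950194 to 103965707, minus strand), a complex III assembly gene that meets a long transcript of the chaperone gene HSP90B1 in GENCODE only, was higher in GFO (173 ± 21.6 against 77.4 ± 14.7 CPM, log2 1.16 ± 0.20, edgeR adjusted p = 0.00288, n = 3 each). HLA-DQB1-AS1, opposite HLA-DQB1, was also higher (820 ± 45.8 against 472 ± 64.4 CPM, adjusted p = 0.0267). These 2 were the only calls among 3122 genes with edgeR, 271 genes had an unadjusted p under 0.05, and DESeq2 called 3. NFKBIA differed by 0.02 ± 0.17 log2 units and was not called. UQCC6 lost its call without REDV replicate 1 (adjusted p = 0.0610), REDV replicate 3 (0.150) or GFO replicate 2 (0.0921), and HLA-DQB1-AS1 without those (0.262, 0.364 and 0.154), GFO replicate 1 (0.381), GFO replicate 3 (0.115) or the filter (0.166). The count was 0 without REDV replicate 1, REDV replicate 3 or GFO replicate 2, 1 without GFO replicate 1 or GFO replicate 3, and 82 in a fit on these 6 libraries alone.

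In RGD against REDV without co-culture, PLCG2 was higher in RGD (84.9 ± 40.6 against 21.2 ± 12.8 CPM, log2 1.96 ± 0.37, edgeR adjusted p = 0.00838, n = 3 each). The chaperone genes HSPA5 (235 ± 92.0 against 107 ± 40.1 CPM) and HSP90B1 (78.3 ± 12.2 against 34.0 ± 6.20 CPM) were higher too, both at adjusted p = 0.0345. The DNA polymerase gene POLQ, opposite the pseudogene RPL7AP11, rose by 1.34 log2 units. The splicing genes SRRM2 and PNN rose by 1.30 and 1.15, and the translation factor gene EIF3A by 1.19, with a small part of their counts opposite SRRM2-AS1, PNN-AS1 and NANOS1. DLSTP1, a pseudogene of a subunit of the ketoglutarate dehydrogenase complex, was lower (569 ± 97.3 against 1142 ± 161 CPM, adjusted p = 0.00113). OPN3 (chromosome 1, 241593124 to 241640369, minus strand), an opsin gene counted opposite the kynurenine enzyme gene KMO, was lower at 65.9 against 133 CPM, and so was RADIL, of cell adhesion, at 53.8 against 114 CPM.

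In all, 18 genes were called higher and 7 lower in RGD against REDV. Of 6 ER stress genes, 2 were called higher (HSPA5 and HSP90B1), or 4 adjusted over the list alone, and 0 lower (camera adjusted p = 0.00205; adjusted p = 0.142 with an estimated correlation). Of 12 mitochondrial mRNAs, MT-ATP8 was called higher, by 0.84 ± 0.19 log2 units (1 adjusted over the list alone; camera 3.90e-05; adjusted p = 0.338 with an estimated correlation). Of 5 cytosolic ribosomal protein genes, 0 were called by edgeR and 0 adjusted over the list alone (camera 0.0424; adjusted p = 0.312 with an estimated correlation). Only DLSTP1 among the 21 named calls, the rest of which include PLCG2, HSPA5 and HSP90B1, stayed called without each library in turn, and it lost the call after thinning (adjusted p = 0.0747). PLCG2 lost its call without REDV replicate 1 (0.140) or REDV replicate 3 (0.0669). RGD replicate 1 stood apart from replicates 2 and 3 (chi-square per degree of freedom 13.2 against replicate 3, and 2.69 between replicates 2 and 3), with the largest exon total (1007040) and the lowest TMM factor (0.797), and 27 genes were called without it. In all, 1 gene was called without REDV replicate 1, 1 without REDV replicate 3, 3 without RGD replicate 2, 67 without RGD replicate 3 and 0 in a fit on these 6 libraries alone.

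GFO against REDV under co-culture gave 0 called genes with edgeR, with 399 at an unadjusted p under 0.05 and 14 called by DESeq2. NFKBIA stood at 437 ± 55.1 against 503 ± 76.0 CPM (log2 -0.20 ± 0.17), BIRC3 at 36.6 ± 10.5 against 30.9 ± 13.6 CPM and CD40LG at 34.5 ± 26.2 against 28.5 ± 13.6 CPM (n = 3 each). Without co-cultured GFO replicate 1, 10 genes were called, and 3 without co-cultured REDV replicate 2. The test of the difference between the co-culture changes in GFO and REDV also called 0 genes with edgeR, with 299 at an unadjusted p under 0.05 and 1 by DESeq2. It called 19 in a fit on the compared groups alone, 3 without co-cultured REDV replicate 2 and 2 without co-cultured GFO replicate 1. In this test NFKBIA differed by -0.22 ± 0.25 log2 units.

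Under co-culture, UQCC6 was lower in RGD than in REDV (57.8 ± 3.06 against 137 ± 10.1 CPM, log2 -1.23 ± 0.25, edgeR adjusted p = 0.0144, n = 3 each). TAMALIN-AS1 was lower as well (327 ± 5.95 against 706 ± 193 CPM, adjusted p = 0.0126), as was the zinc finger gene ZNF710, opposite its antisense RNA (108 against 233 CPM). NFE2L3, a stress transcription factor gene whose locus overlaps HNRNPA2B1, was higher (557 ± 168 against 310 ± 48.0 CPM, adjusted p = 0.0269). NFKBIA differed by -0.02 ± 0.17 log2 units and was not called. In all 4 genes were called higher and 8 lower. The count was 0 without co-cultured REDV replicate 1, co-cultured RGD replicate 2 or co-cultured RGD replicate 3, 2 without co-cultured REDV replicate 3, 20 without co-cultured RGD replicate 1 and 50 without co-cultured REDV replicate 2. It was 23 with DESeq2, 25 in a fit on these 6 libraries alone and 1 without the 3 libraries with over 14% multi-mapped reads.

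Whether co-culture changed a gene differently in RGD than in REDV was tested directly. HSPA5, which fell in RGD, differed by -2.22 ± 0.46 log2 units (edgeR adjusted p = 0.0126), PLCG2 by -2.98 ± 0.68 (adjusted p = 0.0166) and UQCC6 by -1.54 ± 0.33 (adjusted p = 0.0126). TIMMDC1 differed the other way, by 4.79 ± 1.10 (adjusted p = 0.0166), and so did OPN3 (2.05) and RADIL (1.97). In all 23 genes were called higher and 22 lower. Of 6 ER stress genes, 0 were called higher and 1 lower, or 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0482; adjusted p = 0.320 with an estimated correlation). Of 12 mitochondrial mRNAs, 0 were called higher and 1 lower, MT-ATP8, also adjusted over the list alone (camera 0.00324; adjusted p = 0.378 with an estimated correlation). The count was 4 without co-cultured REDV replicate 1, 9 without REDV replicate 1, 16 without REDV replicate 3, 24 without co-cultured REDV replicate 3, 11 without co-cultured RGD replicate 2 and 9 without co-cultured RGD replicate 3. It was 83 without co-cultured REDV replicate 2 and 125 without RGD replicate 3, and of 20 named calls 2 stayed called without each library in turn and 0 in every refit. RPL23P6 was among the 2, and its call ended without the 3 libraries with over 14% multi-mapped reads (adjusted p = 0.214).

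**Figure D4:**
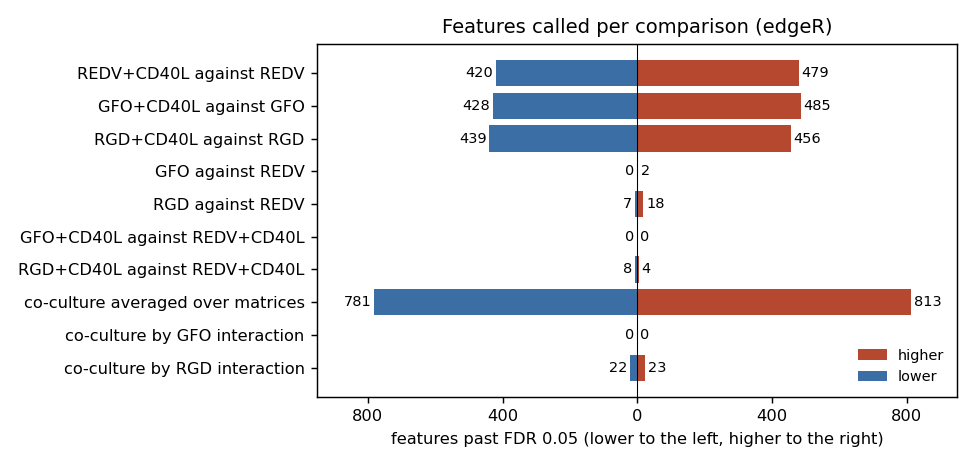
Genes called higher and lower by edgeR at an adjusted p under 0.05 in each of the 10 contrasts, out of 3122 tested. Co-culture gave 895 to 913 calls within a matrix, and the comparisons between matrices gave 0 to 25.

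Contrasts against the same REDV libraries share their chance values. The changes in GFO and RGD against REDV had r = 0.396 across genes without co-culture, whereas unchanged groups simulated against those controls gave 0.494 on average (0.443 to 0.549 in 20 simulations), and the covariance was 0.0717 against 0.0552. Under co-culture r was 0.471 against 0.509 (0.448 to 0.546), and the covariance 0.131 against 0.0906. Only 3 control libraries were at hand, too few to split with at least 2 in each part, so part of any excess may come from the shared controls. The RGD change against REDV without co-culture and the same change under co-culture, which share no libraries, had r = -0.226 across genes, with PLCG2, HSPA5 and UQCC6 among those that differed.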

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

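The tests of what could produce the patterns weighed here and in the observations were chosen after the results were seen, except those said to have been set before. The difference between the co-culture changes in RGD and in REDV was marked out because 45 genes passed edgeR's test of that difference. TIMMDC1 stood at 4.79 log2 units, OPN3, opposite KMO, at 2.05, RADIL at 1.97, and 2 uncharacterised loci, LOC124904883 and LOC124902011, at 2.35 and 2.24. On the other side were RPL23P6 at -3.86, PLCG2 at -2.98, HSP90AA2P at -2.68, MTERF2, opposite TMEM263, at -2.67 and TMED9 at -2.41. RPL23P6 and HSP90AA2P are pseudogenes and may share reads with their parent genes.

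For PLCG2 the difference was made of a fall with co-culture in RGD (-2.34 ± 0.46 log2 units, edgeR adjusted p = 0.000160) and a change in REDV that was not called (0.63 ± 0.47, adjusted p = 0.323). For HSPA5, an endoplasmic reticulum chaperone gene, it was the fall in RGD (-2.21 ± 0.33) against 0.01 ± 0.31 in REDV (adjusted p = 0.980). Both genes were higher in RGD than in REDV without co-culture (1.96 and 1.13), but that contrast uses the same 3 RGD libraries, so a high level in them gives both results. TIMMDC1 had 1 count in RGD and 15 in REDV without co-culture, so its difference rests on few reads. All edgeR values here come from the same 18 libraries, so the 45 genes are not independent replicates.

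Of 100 splits of the same libraries, the real one included and the others drawn at random, 2 gave as many calls. The highest other split gave 51. That share bears on whether chance can be excluded for the 45 genes as a set, not for any gene in it. The split with 51 calls exchanged co-cultured REDV replicate 2 with co-cultured RGD replicate 1. For the difference between GFO and REDV the real count was 0, which all of the 100 splits meet by construction (100 of 100, highest other 5), so that count decides nothing.

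In RGD against REDV without co-culture, genes may differ because more reads of the marked strand were kept in the RGD libraries. The bound for this test was set before the values were seen. Protein-coding genes with no opposite gene, 312 in all, had a median change of 0.156 log2 units (95% bootstrap interval 0.0939 to 0.216), with 62.5% above 0. The interval covers the spread over genes and not over libraries. By library, these genes took 1.86% to 1.96% of tested counts in REDV and 1.87% to 2.06% in RGD, so the groups overlapped. The interval over genes lay above the bound, so by the bound alone the values go with this account. A further requirement, that the called genes lie in this set, was set after that result. Of the calls, 4 of 18 higher and 1 of 7 lower did, against 312 of all 3122 tested genes. With that later requirement the test cannot tell. Of 10 splits of these libraries 1 gave as many as the 25 calls and the highest other gave 7, too few splits to exclude chance.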

How the results depend on the processing

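Of 898 named results 371 were called, and of 6678 refits of called results 772 lost the call, while 0 of 15354 refits passed the threshold with the other sign. The settings below gave counts of called genes that differ from the reported ones by more than 1.5 times, or agreements that moved; the cause was not tested.

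With DESeq2 the counts were 14 for co-cultured GFO against co-cultured REDV, 23 for co-cultured RGD against co-cultured REDV and 1 for the GFO and REDV difference in co-culture change. Without a filter on low counts GFO against REDV gave 1, and the agreement of co-culture changes was 0.220 for REDV and GFO, 0.208 for REDV and RGD and 0.208 for GFO and RGD. With the replicate number as a block the GFO and REDV difference gave 1, and camera lost its ER stress calls in RGD co-culture (adjusted p = 0.0513) and in the RGD difference (0.0655); same-number libraries correlated at 0.0153 on average and others at -0.00760, so numbers were not treated as pairs.

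In fits on the compared groups only, co-culture in RGD gave 592, GFO against REDV 82, RGD against REDV 0, and under co-culture GFO against REDV 1 and RGD against REDV 25. The difference in co-culture change gave 19 for GFO and 14 for RGD. Without the 3 libraries with most multi-mapped reads, co-culture in REDV gave 373, RGD against REDV under co-culture 1 and the RGD difference 4, and REDV and GFO agreed at 0.710. With each library thinned to the smallest, GFO against REDV gave 4, RGD against REDV 0 and GFO against REDV under co-culture 2, and the agreements were 0.728 (REDV and GFO), 0.648 (REDV and RGD) and 0.682 (GFO and RGD). Over all lists and contrasts camera made 10 calls, from 3 lists, against 0 with an estimated correlation and 4 with lists built by the gene on the opposite strand. Fry, which tests a list without setting it against other genes, made 12 calls. Besides mitochondrial mRNAs and ER stress in RGD, these were on average MYC and ribosome biogenesis (adjusted p = 0.00394), ribosomal proteins (0.0134), ER stress (0.0310) and immediate early genes (0.0310). Within a matrix they were MYC and ribosome biogenesis (0.000430) and ribosomal proteins (0.00258) in RGD and immediate early genes in REDV (0.0491), and fry made none between matrices.

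With each library left out in turn, GFO against REDV ranged from 0 (without REDV replicate 1) to 2 (without REDV replicate 2), and RGD against REDV from 1 (without REDV replicate 1) to 67 (without RGD replicate 3). Under co-culture GFO against REDV ranged from 0 (without co-cultured REDV replicate 1) to 10 (without co-cultured GFO replicate 1), and RGD against REDV from 0 (without co-cultured REDV replicate 1) to 50 (without co-cultured REDV replicate 2). Co-culture in RGD ranged from 594 (without co-cultured RGD replicate 2) to 861 (without RGD replicate 3). The GFO difference ranged from 0 (without REDV replicate 1) to 3 (without co-cultured REDV replicate 2), and the RGD difference from 4 (without co-cultured REDV replicate 1) to 125 (without RGD replicate 3). The agreement of REDV and GFO ranged from 0.758 (without co-cultured REDV replicate 2) to 0.800 (without co-cultured GFO replicate 2).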

Other observations

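Some genes with a gene on the opposite strand were read by that partner, and the partners were picked after the data were seen. With co-culture, on average, CFLAR-AS1, opposite the caspase inhibitor gene CFLAR, rose by 0.90 ± 0.08 log2 units (edgeR adjusted p = 3.03e-12), WAKMAR2, opposite TNFAIP3, by 0.87 ± 0.17, and DEXI, opposite CIITA, by 0.87 ± 0.09. HOOK2, opposite the AP-1 gene JUNB, rose by 1.15 ± 0.10, and DTX3L, opposite the interferon-response gene PARP9, by 1.25 ± 0.17. HLA-DQB1-AS1, opposite HLA-DQB1, fell (-1.10 ± 0.10), as did ENOSF1, opposite the thymidylate synthase gene TYMS (-1.70 ± 0.37).

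Lists built from the gene on the opposite strand were added after the data were seen too, and camera made 4 calls with them. By any partner 9 lists had at least 5 tested members, but 0 did by partners opposite a counted exon. All of these list results, with or without a call, therefore rest in part on partners matched by locus only, whose exons may not lie opposite the counts. For ATF4 targets, a stress response, 4 of 5 genes were higher with co-culture in RGD and 0 lower (4 adjusted over the list alone), with a camera adjusted p of 0.00988 (adjusted p = 0.321 with an estimated correlation). In RGD against REDV without co-culture camera called the same list in the lower direction (0.00842; adjusted p = 0.151 with an estimated correlation), with a median of -0.34 log2 units, but edgeR called 0 of its 5 genes, also 0 adjusted over the list alone. For components of B-cell receptor and CBM signalling in RGD against REDV, 1 of 9 was called lower, 0 higher and 8 not, and the same adjusted over the list alone (camera 0.0277, lower direction; adjusted p = 0.132 with an estimated correlation). For DNA replication in GFO against REDV, edgeR called 0 of 6 genes, with 1 lower adjusted over the list alone (camera 0.0330, lower direction; adjusted p = 0.126 with an estimated correlation).

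The opposite-strand lists gave no camera call for the average co-culture change. Of 9 genes of B-cell activation and co-stimulation 3 were higher, 2 lower and 4 not called, with 3 and 2 adjusted over the list alone (camera 0.732; adjusted p = 0.793 with an estimated correlation), and their median was -0.06 and mean 0.53 log2 units. Of 9 B-cell receptor and CBM components 1 was higher, 3 lower and 5 not called, with 1 and 3 adjusted over the list alone (camera 0.474; adjusted p = 0.556 with an estimated correlation). For NF-kB targets 5 of 9 were higher and 3 lower on average, also adjusted over the list alone (camera 0.474; adjusted p = 0.556 with an estimated correlation). For DNA replication 0 of 6 were higher and 4 lower on average (4 adjusted over the list alone; camera 0.405; adjusted p = 0.556 with an estimated correlation).

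The tests of the strand pattern were chosen after it was seen. Reads may have been counted on the strand opposite to the one the library marks, and MT-ND6 stood 5.53 times above the highest mitochondrial mRNA of the other strand, as that account requires. Antisense transcripts as the main RNA, counted on the right strand, would leave messenger RNA counted too, and no library had more than 3.76% of uniquely aligned reads assigned or ambiguous, which speaks against it. If reads were counted on the wrong strand, ZNF740 would carry ITGB7, WAKMAR2 TNFAIP3 and HLA-DQB1-AS1 HLA-DQB1, which lie opposite nearly all of their placed counts. Counting the raw reads again with the other strand setting would test this, since the assigned share should rise and MT-ND6 should drop below the other mitochondrial mRNAs.

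The tests of what lies behind the co-culture changes were chosen after those changes were seen, apart from the bound for the second stromal relation. Lower depth is unlikely to explain them. In each of 5 thinnings to equal exon totals, 80.0% of the averaged calls or more stayed (the mitochondrial share was left as it was). Dilution of lymphoma RNA by 1 factor shared by all genes cannot explain 83 called genes. Each fell more than 1 log2 unit plus 2 standard errors beyond the median gene. Dilution that is weaker for genes also expressed by stromal cells was not tested and stays open. Stromal RNA in the sorted cells could explain 9 genes that each had at most 3 counts in all over the libraries without co-culture. Their sum went with CD40LG over 9 libraries (r = 0.698, exact permutation p = 0.0327, 0.0360 adjusted over 2 relations; Spearman's rho 0.617, exact p = 0.0857; r 0.571 without the 2 farthest libraries), but r was 0.595 (exact p = 0.0898) once depth was taken out. For the 803 other genes that rose, r was -0.692 (exact p = 0.0360; rho -0.683, exact p = 0.0503; -0.474 without the 2 farthest libraries), which met the bound of r below 0 set in advance for no stromal source. The depth adjustment was chosen after both relations were seen: depth went with CD40LG (r = -0.693) and with that mean (0.627), r became -0.459 (exact p = 0.213), and summed CPM gave -0.395, so neither relation tells.

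Of 10 splits of the libraries, 1 gave as many as the 899 calls for co-culture in REDV, 1 as many as the 913 in GFO and 1 as many as the 895 in RGD, with 0 in the highest other split of each. For the 2 calls of GFO against REDV it was 1, with 0 in the highest other. Under co-culture, 2 of 10 gave as many as the 12 for RGD against REDV (highest other 42). These are too few splits to exclude chance. For GFO against REDV under co-culture the real count was 0, which 10 of 10 splits meet by construction (highest other 1). The split with 42 set co-cultured REDV replicates 1 and 3 and co-cultured RGD replicate 1 apart, the libraries with more multi-mapped reads (15.2%, 14.1% and 13.4% against 12.3% to 12.4%). For the averaged co-culture change 1 of 100 splits, the real one, gave as many as the 1594 calls. The others were drawn at random within each matrix, with a median of 0 calls. The highest other gave 1071, with RGD replicate 1 and co-cultured RGD replicate 1 exchanged. Splits that mix co-culture with other libraries put its change into the spread, which lowers their counts. The share bears on whether chance can be excluded for the set, and not on run or lane, which go with co-culture.

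If CD40 ligand drives the NFKBIA rise of 0.92 log2 units, blocking CD40 in co-culture should remove it. The rise of a stromal marker such as COL5A1 should stay if its reads come from stromal cells, which was not tested for that gene. The stromal tests above (r = 0.698 and -0.692) could not tell these sources apart. If the 9 genes nearly absent without co-culture come from stromal cells, a second sort of the same mixture should lower CD40LG and LIF-AS1 together. If RGD raises PLCG2 and HSPA5 before co-culture, new RGD and REDV organoids with at least 6 libraries each should show it, since the test here rested on 3 and its median shift of 0.156 was not separated from strand retention.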
